A study of Mus musculus with 20 samples.

How the data were processed

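RNA was sequenced from germ cells of mice in which Chd4, the gene of a chromatin remodelling ATPase, was targeted with a Cre transgene. The 20 libraries formed 10 groups with 2 replicates each. Of these, 16 were from oocytes at postnatal days 1, 5 and 10 (P1, P5, P10) and 4 were from undifferentiated spermatogonia at P3. The P1, P5 and P3 knockouts (DcKO, Chd4 f/-) and their controls (Dctrl, Chd4 f/+) both carried Ddx4-Cre, so these controls were heterozygous and had Cre. The P10 knockouts (GcKO) were Chd4 f/f with Gdf9-iCre and their controls (Gctrl) were Chd4 f/f without Cre. Non-growing oocytes (NGO) were sampled at every oocyte age and growing oocytes (GO) at P10 only. The labels give a mixed strain background from C57BL/6, 129S1/Sv and FVB/NJ, a low-input library kit with paired reads, no sort or gate, and no statement that replicates were separate animals. The p-values measure the spread between these libraries.

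The authors deposited TPM, a length-scaled expression value, for each library, in a table for the 16 oocyte libraries and another for the 4 spermatogonia libraries. Per the labels, the authors used Trimmomatic 0.39, STAR 2.5.4b, SAMtools 1.9 and featureCounts 2.0.1 with GRCm38. The annotation, the gene lengths, the strandedness and the way TPM was made were not given. The oocyte table held 53722 genes and that of the spermatogonia 55291. The 1569 genes that only the latter listed included 1568 with a symbol in GENCODE M21, all on chromosome Y. Read depth was recovered from TPM and the M21 union exon length of each gene, by finding the scale at which low values became whole reads. At that scale 98.65% to 99.19% of values under 20 reads lay within 0.05 of a whole number.

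Values were analysed as log2(TPM + 1) in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit, and eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested in a comparison and a threshold of 0.05. Genes with TPM of at least 1 in at least 2 libraries of a fit were tested, 20470 in the oocyte fit and 18671 in the spermatogonia fit. All 16 oocyte libraries shared 1 estimate of spread per gene, with 8 residual degrees of freedom and a prior of 3.842. The spermatogonia were fitted alone, with 2 residual degrees of freedom and a prior of 3.973. On this scale the fold changes of genes with low TPM are understated. The comparisons were knockout against control in each of the 5 cell groups, P5 against P1 and GO against NGO in controls, and the differences of the knockout effect between P5 and P1 and between GO and NGO. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

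The comparisons, the filter, the tests, the rule for naming genes, 21 gene lists and the alternative settings were chosen before the data were examined. Each knockout comparison names Chd4, then up to 8 genes with the largest rise and 8 with the largest fall among those past the test that had a mean of at least 5 TPM in 1 group, no overlap between knockout and control libraries, and a symbol that is not a predicted model. Control comparisons and differences of effects name 5 each way, the latter without the overlap criterion. Up to 4 members with the smallest p are named from each list discussed, and any other gene is given with a statement that it was chosen after its values were seen. Some genes that the rule names are not reported here.

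The lists were the NuRD complex, oocyte transcription factors and reserve, oocyte growth with zona pellucida and maternal effect genes, meiotic prophase, primordial germ cell and pluripotency, p53 targets and apoptosis, the piRNA pathway, developmental transcription factors, striated muscle contractile genes, imprinted genes, spermatid genes, the mitotic cell cycle, undifferentiated spermatogonia, differentiating spermatogonia, gonadal supporting cells, gonadal stromal cells, endothelial cells, blood and immune cells, immediate early and dissociation stress, the integrated stress response, and mitochondrially encoded genes. They were tested with camera in limma at a preset correlation of 0.01, two-sided and adjusted over the 21 lists, and again with an estimated correlation. The run with an estimated correlation also has only the residual degrees of freedom, 8 in oocytes and 2 in spermatogonia. Striated muscle genes in spermatogonia had an estimated correlation of -0.0137, yet their unadjusted camera p went from 2.01e-05 to 0.0439. A call lost in that run therefore does not by itself show correlation among the genes of a list. Members past the test were counted over all genes and adjusted over the list alone. Some lists overlap and are not separate results. Stra8, Prdm9, Tex101 and Sycp3 are on both the meiotic and the differentiating spermatogonia lists. Kit, Sohlh1, Sohlh2 and Dazl are on both the latter and the oocyte transcription factor list. The 200 genes that most rose and the 200 that most fell in a control comparison were tested the same way in knockout comparisons with other libraries. Shared calls were tested with Fisher's exact test, two-sided, adjusted over 20 tests.

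The alternatives were a pseudocount of 0.1, no filter, a filter of TPM of at least 5, median scaling, quantile normalization, a fold minimum, a replicate block, a fit of only the groups compared, leaving out each library, camera with an estimated correlation, 100 genes per signature, and an overlap threshold of 0.1. Leaving out a library leaves 1 in its group, which is then assumed to vary like the other groups. A fit of the recovered reads with voom in limma and a fit without mitochondrially encoded genes were added after the data were seen. The test was also run on simulated data with known changes and the same group sizes. Reads that paralogs share (Zscan4, Usp17l, Rhox2, Obox, Khdc1, Fbxw and Igkv genes) and antisense genes such as Kbtbd8os could not be resolved from TPM. The miRNA and snoRNA genes named below (Mir1898, Mir3473a, Snord42b and Snord73a) are short, so few reads can give several TPM.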

Results

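Transcript levels were measured in mouse germ cells with a conditional knockout of Chd4 and in their controls, in 10 groups of 2 libraries. The oocyte groups were knockout and control non-growing oocytes (NGO) at P1, P5 and P10 and growing oocytes (GO) at P10. The remaining groups were knockout and control undifferentiated spermatogonia at P3. Values below are mean TPM ± SD over the 2 libraries of a group (n = 2).

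The recovered depth of replicates 1 and 2 was 17.7 and 19.64 M reads (1 M is 1000000) in P1 controls, 21.04 and 26.35 in P1 knockouts, 21.42 and 21.7 in P5 controls, and 21.93 and 20.67 in P5 knockouts. It was 22.63 and 19.63 M reads in P10 NGO controls, 27.01 and 23.72 in P10 NGO knockouts, 20.56 and 19.51 in GO controls, and 18.93 and 15.33 in GO knockouts. The spermatogonia had 21.1 and 30.07 M reads in controls and 18.91 and 20.73 in knockouts. Between 13952 and 16264 genes reached TPM 1 in P1 and P5 oocytes, 10003 to 11820 in P10 NGO, 11061 to 13517 in GO and 17259 to 18657 in spermatogonia. Dppa3, a maternal effect gene of oocytes, had the highest TPM in all 16 oocyte libraries. The log2 values of the 2 replicates correlated across genes with Pearson r of 0.891 to 0.964 within the 10 groups. The highest r to a library of another group was 0.928 for P1 knockouts, equal to the r between their replicates, and 0.892 for spermatogonia knockouts, whose replicates had 0.898. On the second principal component of the spermatogonia (29.29% of variance) the 2 knockout libraries lay at 74.16 and -59.83 and the controls at -5.22 and -9.11.

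Chd4 (ENSMUSG00000063870, GRCm38 chromosome 6, 125095981 to 125130591, a protein-coding gene) was compared first, over the whole gene rather than the deleted exons. In P1 NGO it fell from 27.95 ± 4.66 TPM in controls to 3.11 ± 1.71 in knockouts, a log2 fold change of -2.87 with a standard error of 0.499 (limma adjusted p = 0.0136). Without control replicate 1, control replicate 2 or knockout replicate 2 the limma adjusted p of Chd4 in P1 NGO DcKO vs Dctrl was 0.101, 0.122 and 0.0910, at log2 fold changes of -3.04, -2.71 and -2.44. It was 0.0626 with a pseudocount of 0.1 and 0.0841 with blocked replicates. At P5 Chd4 was at 6.61 ± 2.36 TPM in knockouts and 16.2 ± 2.43 in controls, with a limma adjusted p of 0.351. In P10 oocytes controls already held little Chd4. Knockouts and controls were at 0.791 ± 0.770 and 1.74 ± 0.157 TPM in NGO (limma adjusted p = 0.615), where knockout replicate 1 was at 1.34 and replicate 2 at 0.25 and the controls at 1.63 and 1.85. They were at 1.09 ± 0.641 and 2.26 ± 0.988 in GO (limma adjusted p = 0.488), where knockout replicate 2 was at 1.54 and control replicate 1 at 1.56. In spermatogonia Chd4 was at 46.0 ± 8.13 TPM in knockouts and 267.5 ± 26.8 in controls, a log2 fold change of -2.52 with a standard error of 0.196 and a limma adjusted p of 0.0671. That value passed at 0.0421 without control replicate 1, at 0.0455 without knockout replicate 2, and at 0.0155 with the filter at TPM 5.

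**Figure D1:**
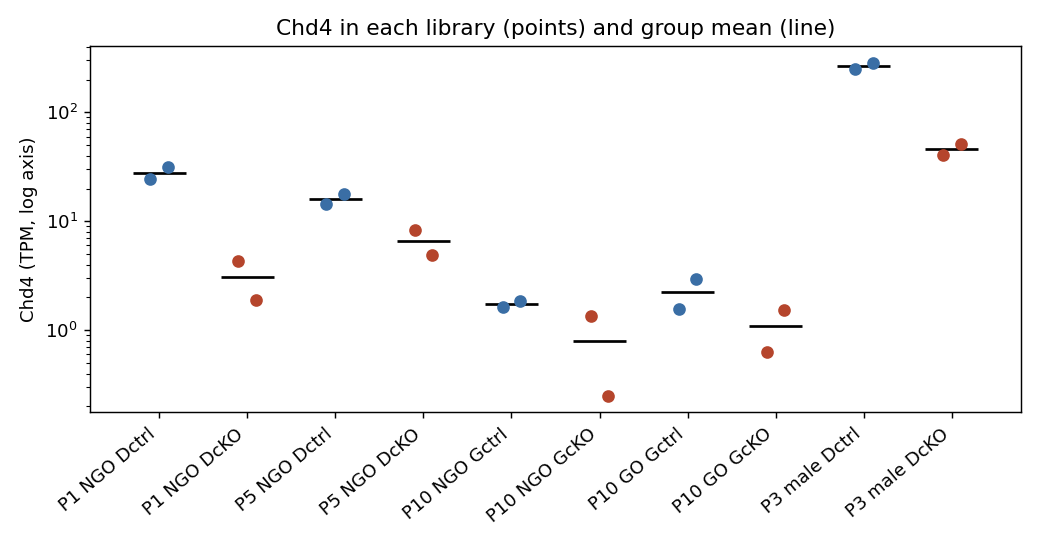
Chd4 level of each library in TPM on a log axis, with 1 point per library, a line at the mean of each group, controls in blue and knockouts in red. The knockout mean lies below the control mean in each of the 5 cell groups, with 3.11 and 27.95 TPM at P1.

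By limma, 348 genes differed between knockout and control in P1 NGO (176 higher and 172 lower in knockouts), 278 in P5 NGO (214 higher, 64 lower), 393 in P10 NGO (209 higher, 184 lower) and 2827 in P10 GO (1866 higher, 961 lower). At an unadjusted p under 0.05 these were 2092, 2421, 3186 and 5217 genes, where chance gives 1024. In spermatogonia the limma count was 0, with 3004 genes at an unadjusted p under 0.05 (2073 higher, 931 lower) where chance gives 934. For spermatogonia voom and quantile normalization each called 1 gene and the filter at TPM 5 called 56. Without spermatogonia control replicate 1, control replicate 2 or knockout replicate 2 the count was 24, 12 and 3.

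**Figure D2:**
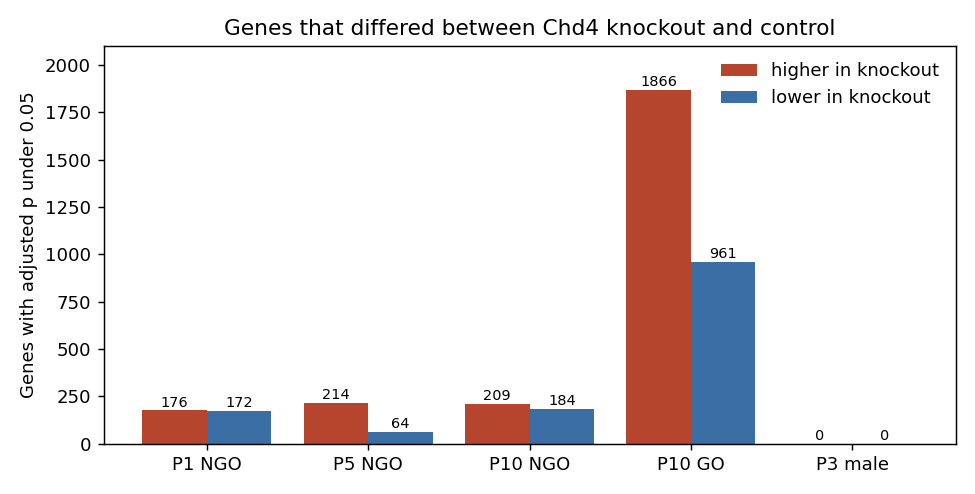
Number of genes past the limma test in each knockout comparison, as bars of genes higher and genes lower in knockouts. P10 growing oocytes have the tallest bars, 1866 higher and 961 lower, and spermatogonia have 0.

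The P1 comparison asks what the Chd4 knockout changes in oocytes around birth, when the follicle reserve forms. Knockout oocytes held less transcript of the oocyte genes Gdf9, Zp3 and Tbpl2, the last a TATA-binding protein of oocytes. They gained the transcription factor Pou3f1 and the retinoic acid binding protein Crabp1. Of the P1 NGO DcKO vs Dctrl genes called by limma 50.6% were higher, and 36.3% with a pseudocount of 0.1 and 36% with voom.

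The largest falls at P1 were in Noto, a homeobox gene, from 79.1 ± 13.3 to 3.52 ± 2.11 TPM (log2 -4.22, limma adjusted p = 0.000109). Tsga10ip fell from 35.5 ± 5.07 to 1.79 ± 0.424 TPM and Tbpl2 from 75.8 ± 15.3 to 5.14 ± 2.47 (limma adjusted p = 0.000266). Mir1898 fell from 14.7 ± 0.506 to 0.543 ± 0.768 TPM, Fbxw16 from 10.9 to 0.143, Fbxw21 from 10.25 to 0.124 and Pter from 9.57 to 0.0697. Gdf9, the growth factor that oocytes send to follicle cells, fell from 32.5 ± 6.95 to 2.67 ± 1.83 TPM (limma adjusted p = 0.00215). Upp1 rose most, from 0.483 ± 0.492 to 55.2 ± 16.1 TPM (limma adjusted p = 0.0169). Arhgdib rose from 6.78 ± 4.53 to 124 ± 8.39 TPM, Pou3f1 from 0.711 ± 0.407 to 27.6 ± 6.58 and Cd24a from 2.27 ± 1.32 to 44.3 ± 16.4. Slc44a3 rose from 1.005 to 26.8 TPM. Chst7 rose from 3.796 ± 1.433 to 61.1 ± 3.78 TPM (limma adjusted p = 0.00149) and Ptgds from 7.46 ± 0.0871 to 110.4 ± 17.3 (limma adjusted p = 0.00131). The ferritin-like gene Fthl17e was listed at 0 in both controls and was at 20.5 ± 1.59 TPM in knockouts.

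Of 35 oocyte growth genes tested at P1, 7 fell and 0 rose (9 and 1 adjusted over the list alone), with a median log2 fold change of -0.31 and a camera adjusted p of 3.69e-05 (adjusted p = 0.418 with an estimated correlation). With Gdf9, its leading members were the linker histone H1f8, which fell from 142.6 ± 22.3 to 39.9 ± 8.71 TPM (limma adjusted p = 0.00284), Zp3, which fell from 104.3 ± 42.4 to 23.5 ± 9.05, and Nlrp4f, which fell from 334 ± 56.4 to 129 ± 8.43. The 13 mitochondrially encoded genes shifted up (11 above 0, camera adjusted p = 0.000453; adjusted p = 0.418 with an estimated correlation), with 0 past the test over all genes and 3 that rose adjusted over the list alone. Their share of TPM was 3.41% and 3.67% in knockouts and 2.91% and 3.11% in controls. Of 16 integrated stress response genes 13 lay above 0 (camera adjusted p = 0.0433; adjusted p = 0.418 with an estimated correlation), with 0 past the test over all genes or adjusted over the list alone. That list gave 0.214 without control replicate 1 and 0.354 without knockout replicate 1. The other 18 lists had camera adjusted p from 0.0668 to 0.984. Among their members, Crabp1 rose from 97.0 ± 32.7 to 1180 ± 81.6 TPM (limma adjusted p = 0.00793), Lin28a from 10.95 ± 5.49 to 43.3 ± 5.32 and Serpine2 from 3.99 to 26.95 ± 0.718. The T-box gene Tbx1 rose from 0.0189 to 2.25 TPM, while the piRNA pathway gene Gtsf1 fell from 3749 ± 40.8 to 1916 ± 114 TPM (limma adjusted p = 0.00115) and Cd9 fell from 768 to 314.

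Without P1 control replicate 1, control replicate 2 or knockout replicate 1 the P1 count was 71, 106 and 187. Of the 16 genes named by size, Chst7, Ptgds, Noto, Tsga10ip, Tbpl2 and Gdf9 passed whichever library was left out, as did H1f8 and Gtsf1 among the 10 list members, while 9, 7, 4 and 4 of the 16 missed the threshold without control replicate 1, control replicate 2, knockout replicate 1 and knockout replicate 2. Voom ended the calls of 6 of the 16, Gdf9, Ptgds and Tbpl2 among them, and of Gtsf1, Crabp1 and Zp3, and blocked replicates ended 9 of the 16, Gdf9, Pou3f1 and Upp1 among them, and 8 of the 10 list members (all but H1f8 and Gtsf1).

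The P5 comparison asks the same of oocytes once primordial follicles have formed. Knockout oocytes held more transcript of Syce2 and Sycp1, which form the synaptonemal complex in meiotic prophase, and less of the maternal effect genes Ooep and Nlrp14. Genes higher in knockouts made up 77.0% of the calls, and 66.1% with the filter at TPM 5.

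Among meiotic prophase genes, Syce2 rose from 998 ± 112 to 1783 ± 147 TPM (log2 0.84, limma adjusted p = 0.00595), Hormad1 from 191 to 659 ± 148 (limma adjusted p = 0.0238) and Sycp1 from 468 ± 143 to 1121 ± 94.1 (limma adjusted p = 0.0306). Tex101, a germ cell surface gene on the same list, rose from 7.21 ± 8.96 to 83.6 ± 68.1 TPM (limma adjusted p = 0.0397). Of the 36 genes on that list 4 rose and 0 fell (5 and 0 adjusted over the list alone), 29 lay above 0, and the camera adjusted p was 7.87e-06 (adjusted p = 0.262 with an estimated correlation). Of 35 oocyte growth genes 2 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.52 and a camera adjusted p of 5.97e-06 (adjusted p = 0.262 with an estimated correlation). These were Ooep, which fell from 1448 ± 252 to 836 ± 162 TPM (limma adjusted p = 0.0213), and Nlrp14, which fell from 1125 ± 88.9 to 356 ± 37.2 (limma adjusted p = 0.0341).

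The largest rises at P5 included Inha, an inhibin subunit, from 1.13 ± 1.49 to 28.5 ± 21.7 TPM (limma adjusted p = 0.0174), and Magea5, an X-linked cancer-testis gene, from 1.08 ± 1.52 to 20.5 ± 0.721 (limma adjusted p = 0.00720). Aadac rose from 0.884 ± 1.25 to 19.5 ± 8.18 TPM, Akr1c14 from 0.0342 to 11.6, Pcolce from 0.665 to 14.1 ± 2.17 and Cers3 from 2.04 to 27.4 ± 7.94. The snoRNA gene Snord42b, a short locus, was listed at 0 in controls and was at 8.69 ± 3.86 TPM in knockouts. Elobl fell from 1897 ± 112 to 523 ± 188 TPM (log2 -1.90, limma adjusted p = 0.00720) and the deadenylase gene Cnot7 from 187 ± 14.9 to 53.4 ± 25.7 (limma adjusted p = 0.0217). Rpusd1 fell from 17.5 to 1.81 TPM, Angptl6 from 21.3 to 3.30, Pkib from 24.8 to 5.35, Hsd17b2 from 8.98 to 0.988, Apba3 from 5.90 to 0.695 and H2-DMb1 from 5.79 to 0.201.

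Further lists shifted at P5. Of 14 genes of differentiating spermatogonia 1 rose (7 adjusted over the list alone), Tex101, which is also on the meiotic list. The camera adjusted p was 0.000987 (adjusted p = 0.262 with an estimated correlation). Of 13 mitochondrially encoded genes mt-Nd1 rose, from 2405 ± 144 to 3967 ± 425 TPM (3 rose adjusted over the list alone), with a camera adjusted p of 0.000987 (adjusted p = 0.314 with an estimated correlation). Their share of TPM was 2.16% and 2.29% in knockouts and 1.69% and 1.93% in controls. Of 23 supporting cell genes Inha rose (4 adjusted over the list alone), 17 lay above 0, and the camera adjusted p was 0.0171 (adjusted p = 0.262 with an estimated correlation). Muscle genes (camera adjusted p = 0.0403; adjusted p = 0.262 with an estimated correlation), imprinted genes (0.0298; adjusted p = 0.314 with an estimated correlation) and blood genes (0.0253; adjusted p = 0.314 with an estimated correlation) shifted up, with 0 members past the test over all genes and 2 each that rose adjusted over the list alone. Mitotic cell cycle genes shifted down (camera adjusted p = 0.0403; adjusted p = 0.391 with an estimated correlation), with 0 members past either test. The other 12 lists had camera adjusted p from 0.107 to 0.842, and from them the pluripotency gene Dppa5a fell from 3616 to 2034 TPM (limma adjusted p = 0.00629).

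On the second principal component of the oocytes (15.14% of variance) the 2 P5 controls stood apart, at 33.95 and 3.35, and the knockouts lay at 43.34 and 58.67. The P5 count was 22 without control replicate 2, 22 without knockout replicate 2, 104 without knockout replicate 1, 56 with the filter at TPM 5, and 0 when only the P5 groups were fitted or replicates were blocked, so none of the 16 genes named by size and 7 list members passed throughout. Without control replicate 2 the supporting, muscle, blood and mitotic lists had camera adjusted p of 0.101, 0.129, 0.129 and 0.129 and list imprinted genes in P5 NGO DcKO vs Dctrl had 0.0976, without knockout replicate 2 the blood list had 0.131 and the supporting, muscle and imprinted lists also missed the threshold, and without knockout replicate 1 the mitotic list had 0.147 and the muscle list missed it.

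The comparison of P5 with P1 controls describes the age change against which these effects can be read. Between P1 and P5 control oocytes gained transcripts such as the zona pellucida gene Zp1 and lost others such as the synaptonemal complex gene Syce3. By limma 962 genes differed (556 higher and 406 lower at P5), with 249 and 356 without P1 control replicates 1 and 2 and 408 and 486 without P5 control replicates 1 and 2. Elobl rose from 17.1 ± 6.64 to 1897 ± 112 TPM (log2 6.76, limma adjusted p = 1.16e-07), Khdc1a from 7.81 to 591 ± 40.6, Khdc1c from 0.229 to 58.7, Zp1 from 12.75 ± 0.236 to 454.5 ± 55.7 and Oas1d from 47.5 to 1546 ± 21.5. Tex101 fell from 510.2 ± 39.0 to 7.21 ± 8.96 TPM (limma adjusted p = 0.000647) and Syce3 from 457 ± 64.8 to 20.9 ± 4.06 (limma adjusted p = 0.00180). Krt8 fell from 63.5 to 4.04 TPM and Taf7l from 285 ± 9.08 to 23.2 ± 26.1, while Sval1 was at 36.7 ± 18.4 TPM at P1 and listed at 0 at P5. Krt8, Sval1 and Taf7l missed the threshold without either P1 library, and Sval1 also without either P5 library.

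Oocyte growth genes rose with age (22 of 35, and 26 adjusted over the list alone), with a camera adjusted p of 5.79e-29, and this was the only one of 45 list calls that held with an estimated correlation (0.0128). Ooep rose from 311 to 1448 TPM and Nlrp14 from 73.7 to 1125. Meiotic genes fell (9 of 36, and 10 adjusted over the list alone; camera adjusted p = 1.86e-05; adjusted p = 0.259 with an estimated correlation). Syce2 fell from 1925 to 998 TPM and Sycp1 from 1374 to 468. Mitochondrially encoded genes fell (4 of 13, and 7 adjusted over the list alone; camera adjusted p = 1.95e-08; adjusted p = 0.252 with an estimated correlation). The transcript mt-Nd1 fell from 5168 to 2405 TPM. Primordial germ cell genes shifted up (3 of 17 rose, 4 adjusted over the list alone; camera adjusted p = 0.00727; adjusted p = 0.252 with an estimated correlation), with Dppa5a from 718 to 3616 TPM. Supporting cell genes shifted down (2 of 23 fell, and 5 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.00564; adjusted p = 0.252 with an estimated correlation). Stress response genes shifted up (1 of 16 rose, 2 adjusted over the list alone; camera adjusted p = 0.0288; adjusted p = 0.304 with an estimated correlation), with Nupr1 from 10.8 to 96.1 TPM. The piRNA list shifted down (1 of 23 fell, also adjusted over the list alone), the mitotic list up (2 of 25 rose, 3 adjusted over the list alone) and the differentiating spermatogonia list down (3 of 14 fell and 1 rose, also adjusted over the list alone). Each of these 3 had a camera adjusted p of 0.0443 (adjusted p = 0.441, adjusted p = 0.603 and adjusted p = 0.441 with an estimated correlation). The stress response, mitotic, piRNA, germ cell and differentiating spermatogonia lists missed the threshold without at least 1 library, with 0.169 for stress genes without P1 control replicate 1, 0.105 without P5 control replicate 1, and 0.263 and 0.171 for mitotic genes without P1 control replicate 1 and P5 control replicate 2. Without P1 control replicate 2 and P5 control replicate 1 the piRNA list had 0.145 and 0.307, without P1 control replicate 2 and P5 control replicate 2 the differentiating list had 0.144 and 0.448, and without P1 control replicate 1 the germ cell list had 0.0664. The other 12 lists ranged from 0.116 to 0.831.

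The P10 NGO comparison asks what the Chd4 knockout with Gdf9-iCre changes in resting oocytes. Knockout oocytes gained transcripts that controls held near 0, Adh4, Arhgdib and Meioc among them, and lost others such as Pudp and Ifitm6. Adh4, an alcohol dehydrogenase gene, rose from 0.183 ± 0.120 to 81.9 ± 1.67 TPM (log2 6.13, limma adjusted p = 0.00583) and Arhgdib from 0.118 to 69.3 ± 12.1 (limma adjusted p = 0.00459). The meiotic regulator Meioc rose from 0.415 to 92.4 ± 59.7 TPM, Ly6k from 0.173 to 44.2 ± 11.4, Mzt2 from 0.317 to 39.6 ± 4.77 and the X-linked gene Klhl13 from 0.320 to 37.24 ± 16.97 (limma adjusted p = 0.000792). H2bu2 rose from 0.866 to 60.6 ± 51.3 TPM, and Ifi27 was listed at 0 in controls and at 27.5 ± 16.3 in knockouts. Pudp fell from 34.05 ± 6.75 to 0.394 TPM (limma adjusted p = 0.00117), Tcl1b1 from 25.3 to 0.213, Dnajc5b from 20.5 to 0.0421 and Pigc from 21.9 to 0.183. Ifitm6 fell from 32.5 ± 8.31 to 0.684 TPM and Ifit1bl2 from 95.6 ± 24.9 to 5.42. Snord73a and the histone gene H4c8 were listed at 0 in knockouts and were at 57.5 ± 42.7 and 18.96 ± 0.295 TPM in controls.

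Of 35 oocyte growth genes 31 lay below 0 in P10 NGO, with a median of -0.51 and a camera adjusted p of 2.49e-05 (adjusted p = 0.511 with an estimated correlation), 0 past the test over all genes and 2 that fell adjusted over the list alone. All 13 mitochondrially encoded genes lay above 0 (camera adjusted p = 1.40e-06; adjusted p = 0.511 with an estimated correlation). Of these mt-Nd1 rose from 2408 ± 453 to 3954 ± 744 TPM (7 rose adjusted over the list alone), and their share of TPM was 4.62% and 6.22% in knockouts and 4.31% and 3.39% in controls. Of 23 supporting cell genes 17 lay above 0 (camera adjusted p = 0.0434; adjusted p = 0.511 with an estimated correlation), and 1 rose (2 adjusted over the list alone), the gap junction gene Gja1, from 0.0854 to 14.8 ± 0.925 TPM. The other 18 lists ranged from 0.0882 to 0.962. From them Sycp3 rose from 2420 ± 4.55 to 3742 ± 182 TPM (limma adjusted p = 0.0375), Tex19.1 from 1.56 to 25.1 ± 11.3, Zdbf2 from 0.783 to 13 and the sperm lactate dehydrogenase gene Ldhc from 0.394 to 21.3 ± 5.86 (limma adjusted p = 0.00171). Majin was listed at 0 in controls and was at 23.4 TPM in knockouts. Ddx4, an RNA helicase gene of germ cells, fell from 375 ± 13.3 to 145 ± 45.5 TPM (limma adjusted p = 0.0423) and Gadd45b from 5.05 to 0.189.

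The P10 NGO count was 0 when only these groups were fitted, 28 with blocked replicates, and 639 and 1260 without control replicate 1 and knockout replicate 1, the knockout library with more Chd4. Leaving out single libraries ended the calls of Meioc and Mzt2 (without control replicate 2 or knockout replicate 2), Ly6k (without either or control replicate 1), Dnajc5b (without control replicate 2), Snord73a (without any of the 4) and 8 of the 9 list members (all but Ldhc), and the oocyte growth list had a camera adjusted p of 0.0820 without control replicate 2, while the supporting cell list had 0.110, 0.159 and 0.164 without control replicates 1 and 2 and knockout replicate 1, and also missed the threshold without knockout replicate 2.

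The P10 GO comparison asks what the Chd4 knockout changes in oocytes that have started to grow, and it had the most calls of the 5 knockout comparisons. Knockout growing oocytes held transcripts that were low in control growing oocytes, among them the meiotic genes Stra8 and Sycp3 and the oocyte transcription factor Sohlh1. They also gained Zscan4a and the apoptosis genes Pmaip1 and Bax, while Gabrr3, Gpr1, Obox1 and Obox2 fell. Of the P10 GO GcKO vs Gctrl genes called by limma 66.0% were higher in knockouts, and 55.4% with median scaling and 52.6% with quantile normalization.

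Stra8, which starts meiosis in response to retinoic acid, rose from 0.110 ± 0.0507 to 243 ± 6.25 TPM (log2 7.78, limma adjusted p = 0.000491). Zfp119b rose from 0.734 to 292 ± 1.13 TPM (limma adjusted p = 5.25e-06) and Bex3 from 1.98 ± 0.507 to 316 ± 33.1 (log2 6.74, limma adjusted p = 3.92e-07). Zscan4a, of a gene family of the early embryo and typed as an unprocessed pseudogene in GENCODE M21, rose from 0.0583 to 95.4 ± 40.7 TPM (limma adjusted p = 2.91e-05) and the deubiquitinase gene Usp17lb from 0.0422 to 131 ± 23.0 (limma adjusted p = 9.02e-07). The homeobox gene Rhox2d rose from 0.290 to 162 ± 21.6 TPM and Mir3473a from 0.859 to 253 ± 171, while Igkv4-63 was listed at 0 in controls and at 86.7 ± 0.0463 in knockouts. The receptor genes Gabrr3 (62.5 ± 11.7 to 0.163 TPM, limma adjusted p = 3.51e-06), Gpr1 (63.8 ± 16.1 to 0.358, limma adjusted p = 3.51e-06) and Npffr2 (48.7 to 0.134) fell. Lrrtm4 fell from 45.7 ± 7.99 to 0.859 TPM (limma adjusted p = 0.000366), Tex26 from 60.9 ± 23.2 to 0.149, Kbtbd8os from 79.2 to 0.517, Igkv13-87, an immunoglobulin pseudogene in GENCODE M21, from 290 ± 159 to 22.6 ± 31.3 and Ccl2 from 102.4 to 7.92 ± 11.03.

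**Figure D3:**
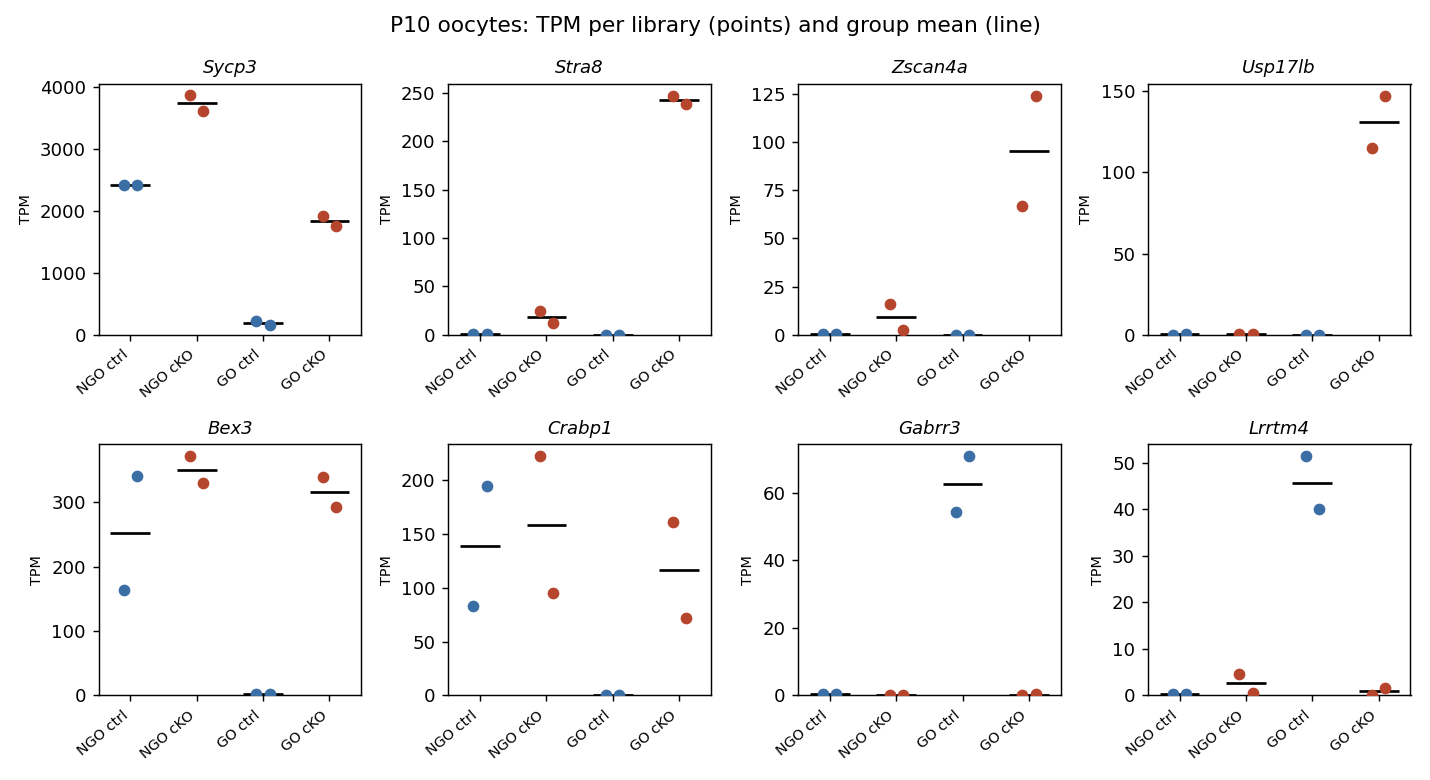
TPM of Sycp3, Stra8, Zscan4a, Usp17lb, Bex3, Crabp1, Gabrr3 and Lrrtm4 in the P10 libraries of non-growing and growing oocytes. Each library is 1 point, with controls in blue and knockouts in red. In growing oocytes the first 6 are higher and the last 2 lower in both knockout libraries than in both controls, with Sycp3 means of 1841 and 191 TPM.

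Among 36 meiotic genes 12 rose and 5 fell in knockout GO (13 and 6 adjusted over the list alone; camera adjusted p = 0.286). Sycp3 rose from 191 ± 52.7 to 1841 ± 113 TPM (limma adjusted p = 3.55e-07), Syce1 from 17.6 ± 2.27 to 287 ± 87.2 (limma adjusted p = 6.55e-07) and the meiotic cohesin gene Smc1b from 198 ± 0.297 to 686 ± 276 (limma adjusted p = 0.000198), while Sycp2 fell from 83.0 ± 7.74 to 10.99 ± 0.507 (limma adjusted p = 0.000196). Genes of differentiating spermatogonia shifted up, with 4 of 14 that rose and 0 that fell (5 and 1 adjusted over the list alone) and a camera adjusted p of 0.0223 (adjusted p = 0.828 with an estimated correlation). With Stra8 and Sycp3, which are also on the meiotic list, these were Sohlh1, from 1.03 ± 0.133 to 33.9 ± 16.04 TPM (limma adjusted p = 4.43e-06), and Crabp1, from 0.662 to 117 ± 62.6 (limma adjusted p = 3.40e-05). That list missed the threshold with the filter at TPM 5, with only these groups fitted, with blocked replicates and with voom.

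Of 19 oocyte transcription factor and reserve genes 4 rose and 0 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.695). With Sohlh1 these were Figla, from 392 ± 107 to 859 ± 150 TPM (limma adjusted p = 0.00441), Tbpl2 from 492 ± 139 to 1278 ± 20.02 and Nobox from 71.5 ± 0.709 to 141 ± 5.61. Oocyte growth genes went both ways, with 4 of 35 that rose and 9 that fell (6 and 10 adjusted over the list alone; camera adjusted p = 0.286). Dppa3 rose from 46020 ± 1101 to 99910 ± 7878 TPM (log2 1.12, limma adjusted p = 4.43e-06), a change that quantile normalization sets to 0 because Dppa3 ranked first in every oocyte library. Obox2 fell from 2005 ± 116 to 136 ± 95.6 TPM (limma adjusted p = 0.00142), Obox1 from 872 ± 4.22 to 108 ± 77.7 (limma adjusted p = 0.00167) and the DNA methylation cofactor Dnmt3l from 7.94 ± 5.63 to 0.0669 (limma adjusted p = 0.000320).

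Of 28 p53 targets and apoptosis genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.712). The BH3-only gene Pmaip1 rose from 0.633 ± 0.214 to 92.6 ± 4.38 TPM (limma adjusted p = 7.65e-06), Bax from 1.63 ± 2.07 to 14.8 ± 0.589 (limma adjusted p = 0.00304), Cdkn1a from 0.243 to 11.1 ± 7.56 (limma adjusted p = 0.00462) and Perp from 8.89 ± 8.21 to 40.8 ± 0.220 (limma adjusted p = 0.0135). In the piRNA list 1 of 23 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.475), with Mael from 57.4 to 131 TPM, Tdrd12 from 128 to 18.4 and Rnf17 from 214 to 74.6. From the remaining lists, which were not called, the ciliary gene Tekt1 rose from 1.20 to 56.3 ± 4.66 TPM, Asns from 0.0963 to 28.1 ± 2.86, Snrpn from 16.4 to 112.5 ± 35.1 and Gadd45b from 0.582 to 17.97, and Clu was listed at 0 in controls and at 8.13 ± 1.13 in knockouts. Isl1 fell from 87.5 to 6.41 TPM, Plagl1 from 15.4 to 0.337 and Slc7a11 from 24.85 to 4.47. The 20 lists not called had camera adjusted p from 0.286 to 0.907.

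The GO count was 1744 and 1749 without control replicates 1 and 2 and 1527 when only these groups were fitted. Of the 16 genes named by size, Igkv13-87 missed the threshold without control replicate 1 and Ccl2 without control replicate 2 or knockout replicate 1, and so did Figla (without control replicate 1), Tbpl2 (without control replicate 1 or either knockout), Nobox (without either control or knockout replicate 2) and Perp (without control replicate 2 or either knockout). With only these groups fitted Ccl2, Igkv13-87 and 17 of 48 list members, Bax, Perp, Mael and Dnmt3l among them, missed it, as did 8 of 48 with voom, Figla and Smc1b among them, and 10 with blocked replicates and 4 with median scaling, Nobox among both.

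The comparison of control GO with control NGO gives the change that growth brings at P10. By limma 4968 genes differed (2257 higher and 2711 lower in GO). Of the GO vs NGO P10 in Gctrl genes called 45.4% were higher, and 64.1% with median scaling. Obox1 rose from 6.07 ± 0.286 to 872 ± 4.22 TPM (log2 6.95, limma adjusted p = 3.63e-06), Oosp3 from 6.16 to 738.5 ± 86.7, Nlrp9c from 5.80 to 676 ± 21.1, Tcstv3 from 1.65 to 287 and D16Ertd519e from 3.34 to 425. Bex3 fell from 252.5 ± 125 to 1.98 TPM (limma adjusted p = 2.32e-07), Crabp1 from 139 ± 78.6 to 0.662, Uqcc3 from 289 ± 35.2 to 2.27 and Pard3bos3 from 142 to 1.01. Oocyte growth genes rose (26 of 35 rose and 2 fell, 29 and 3 adjusted over the list alone; camera adjusted p = 7.79e-15; adjusted p = 0.0982 with an estimated correlation). Omt2a rose from 171 to 5658 TPM, H1f8 from 162 to 1531 and Oosp1 from 6.82 to 647. Meiotic genes fell (14 of 36 fell and 1 rose, 14 and 2 adjusted over the list alone; camera adjusted p = 0.000770; adjusted p = 0.302 with an estimated correlation). Sycp3 fell from 2420 to 191 TPM and Syce1 from 684 to 17.6. Oocyte transcription factors fell (7 of 19, and 9 adjusted over the list alone; camera adjusted p = 0.0131; adjusted p = 0.197 with an estimated correlation). Sohlh1 fell from 92.2 to 1.03 TPM and Figla from 1543 to 392. Pmaip1 fell from 26.7 to 0.633 TPM. Genes of differentiating spermatogonia (5 of 14 fell, 7 adjusted over the list alone; camera adjusted p = 0.00437; adjusted p = 0.289 with an estimated correlation) and mitochondrially encoded genes (9 of 13 fell, 10 adjusted over the list alone; 2.71e-06; adjusted p = 0.197 with an estimated correlation) shifted down. Genes of primordial germ cells (7 of 17 rose and 1 fell, 8 and 2 adjusted over the list alone; camera adjusted p = 0.00257; adjusted p = 0.197 with an estimated correlation) and undifferentiated spermatogonia (7 of 20 rose and 2 fell, 8 and 2 adjusted over the list alone; 0.0177; adjusted p = 0.197 with an estimated correlation) shifted up. The other 14 lists ranged from 0.133 to 0.927. Without NGO control replicate 1 and GO control replicate 1 the camera adjusted p of list oocyte transcription factors and reserve in GO vs NGO P10 in Gctrl was 0.0856 and 0.0516, and without GO control replicate 2 that of list undifferentiated spermatogonia in GO vs NGO P10 in Gctrl was 0.0591.

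The growth change was then set against the knockout effect with the GO controls split, a test chosen after the results were seen, so that no library stood on both sides. The 200 genes that most fell with growth by 1 GO control shifted up in knockout GO against the other control, with medians of 0.82 and 0.98 in the 2 splits (camera adjusted p = 1.41e-38 and 9.34e-46; adjusted p = 0.000618 with an estimated correlation in each). The 200 that most rose with growth shifted down, with medians of -1.30 and -1.23 (camera adjusted p = 4.79e-41 and 3.14e-29; adjusted p = 0.000574 and adjusted p = 0.000618 with an estimated correlation).

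The spermatogonia comparison asks whether the Chd4 knockout changes male germ cells at P3. No gene passed the limma test, so the values here are differences that did not reach the threshold. Knockout cells had lower levels of the stem cell genes Nanos2 and Zbtb16 and higher levels of the imprinted genes Dlk1 and Cdkn1c and the muscle gene Des. Nanos2 was at 0.236 ± 0.333 TPM in knockouts and 11.4 ± 4.44 in controls (limma adjusted p = 0.143), and Zbtb16 at 49.3 ± 7.30 and 96.0 ± 19.3 (limma adjusted p = 0.178). The undifferentiated spermatogonia list had 16 of 29 genes above 0 (1 lower adjusted over the list alone; camera adjusted p = 0.691).

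Lists with 0 genes past the test over all genes shifted together in spermatogonia. Mitotic cell cycle genes were lower (22 of 25 below 0, camera adjusted p = 1.23e-06; adjusted p = 0.307 with an estimated correlation; 0 adjusted over the list alone). Cdc20 was at 248 ± 35.0 TPM in knockouts and 409.5 ± 0.894 in controls and Ccnb1 at 234 and 359. Genes of differentiating spermatogonia were higher (9 of 14 adjusted over the list alone, camera adjusted p = 5.05e-05; adjusted p = 0.307 with an estimated correlation). Ly6k was at 68.6 ± 11.1 and 4.40 ± 1.48 TPM and Dnmt3b at 62.7 and 24.0. Imprinted genes were higher (9 of 25, with 1 lower, adjusted over the list alone, camera adjusted p = 8.90e-05; adjusted p = 0.307 with an estimated correlation). Dlk1, which is also on the stromal list, was at 100 ± 4.54 and 19.6 ± 1.22 TPM and Cdkn1c at 77.4 ± 5.77 and 15.04 ± 5.39. Striated muscle genes were higher (4 of 18 adjusted over the list alone, camera adjusted p = 8.90e-05; adjusted p = 0.307 with an estimated correlation). Des was at 16.2 and 1.19 TPM and Tnni2 at 34.6 and 5.23. Developmental transcription factors were higher (1 of 34 adjusted over the list alone, camera adjusted p = 5.84e-04; adjusted p = 0.307 with an estimated correlation). Hoxb1 was at 17.2 ± 3.56 and 0.593 TPM. Meiotic genes were higher (3 of 36 adjusted over the list alone, camera adjusted p = 0.0108; adjusted p = 0.307 with an estimated correlation). Meioc was at 60.9 and 23.9 TPM.

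Genes of somatic cells were higher in knockout spermatogonia in the same comparison. Stromal genes had 13 of 14 above 0 (4 adjusted over the list alone, camera adjusted p = 5.05e-05; adjusted p = 0.307 with an estimated correlation). Pdgfrb was at 12.6 and 0.701 TPM and Col1a1 at 25.8 ± 2.28 and 6.71 ± 1.56. Supporting cell genes had 21 of 26 above 0 (5 adjusted over the list alone, camera adjusted p = 0.00843; adjusted p = 0.307 with an estimated correlation). Krt18 was at 314 ± 87.2 and 53.8 ± 7.57 TPM and Serpine2 at 155 ± 0.626 and 43.0 ± 16.4. Endothelial genes (5 of 13 adjusted over the list alone, camera adjusted p = 0.00424; adjusted p = 0.314 with an estimated correlation) and blood genes (2 of 7 adjusted over the list alone, camera adjusted p = 0.0114; adjusted p = 0.307 with an estimated correlation) were higher. Fcer1g was at 298 ± 40.7 and 82.3 ± 10.7 TPM. Immediate early genes were higher (3 of 17 adjusted over the list alone, camera adjusted p = 0.00713; adjusted p = 0.408 with an estimated correlation). Zfp36 was at 55.2 and 20.2 TPM. The other 10 lists, p53 targets with Bbc3 at 8.52 and 0.0272 TPM and the NuRD complex with Chd3 at 45.4 and 19.4 TPM among them, ranged from 0.0878 to 0.881. Leaving out a library ended the call of 4 of these 11 lists, developmental factors (either knockout), immediate early genes (control replicate 1), and blood and meiotic genes (control replicate 2).

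Calls were compared between the knockout comparisons, which share no libraries. The genes higher in knockouts at P1 and P5 shared 29, against 1.84 expected if the calls were independent (Fisher's exact adjusted p = 3.60e-25), and the lower ones 14 against 0.54. P10 NGO and GO shared 65 higher against 19.05 and 23 lower against 8.64. P1 and GO shared 41 higher against 16.04 and 15 lower against 8.07, and P5 and GO 40 against 19.51 and 8 against 3.00. P1 and P10 NGO shared 12 against 1.80 and 5 against 1.55, and P5 and P10 NGO 7 against 2.18 and 5 against 0.58. Of the genes lower at P1, at P5 and in P10 NGO, 9, 8 and 20 were higher in GO, and of the genes higher there 3, 4 and 10 were lower in GO. These opposite calls were not tested against an expected count, so they are not read as reversals of the effect. Across genes, which are not independent replicates, Pearson r of the fold changes was 0.318 between P1 and P5 and 0.138 to 0.197 between the other oocyte pairs. All oocyte comparisons share each gene's spread estimate. Spermatogonia had no calls to share at 0.05. At a threshold of 0.1 for the calls, their 32 higher genes shared 15 with GO against 3.92 expected (Fisher's exact adjusted p = 3.63e-06), 5 with P5 against 0.51, 4 with P1 against 0.41 and 4 with P10 NGO against 0.70, and their 3 lower genes shared Chd4 with P1 (Fisher's exact adjusted p = 0.0355) and 0 with the others. The oocyte pairs stayed past the test at 0.1, with Fisher's exact adjusted p of up to 0.00322. With only the groups compared in each fit P1 and GO shared 49 higher and 13 lower genes and the other pairs 0, since P5 and P10 NGO then had no calls.

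Of the shared genes, Zfp54, a zinc finger gene chosen after its values were seen, rose in all 4 oocyte comparisons. Zfp54 was listed at 0 in P1 controls and was at 2.85 TPM in P1 knockouts, and it rose from 5.10 to 30.3 TPM at P5, from 0.532 to 34.6 in P10 NGO and from 7.55 to 347.7 in P10 GO (limma adjusted p = 0.0412, 0.0204, 0.000792 and 7.61e-06). Elobl, named above, fell in the 3 NGO comparisons, from 17.1 to 5.61 TPM at P1, from 1897 to 523 at P5 and from 3707 to 1149 in P10 NGO (limma adjusted p = 0.0212, 0.00720 and 0.00992).

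The 200 genes that most rose with growth at P10 in controls shifted down in P1 knockouts, where 10 fell and 2 rose (camera adjusted p = 0.00166; adjusted p = 0.748 with an estimated correlation). With 100 genes that adjusted p was 8.11e-05 (adjusted p = 0.347 with an estimated correlation). The other 7 tests of growth and age signatures had camera adjusted p from 0.0535 to 0.825. With 100 genes the P5 rise list shifted down in P10 NGO (36 above and 60 below 0) and the growth fall list shifted down in P5 (41 above and 59 below 0), each with a camera adjusted p of 0.0339 (adjusted p = 0.778 with an estimated correlation for each). In the knockout comparisons the median, the mean and the camera direction differed in sign only for lists that were not called, oocyte transcription factors and piRNA genes at P1, germ cell and undifferentiated spermatogonia genes at P5, NuRD, piRNA, imprinted and immediate early genes in P10 NGO, NuRD, germ cell, muscle and undifferentiated spermatogonia genes in GO, and germ cell, piRNA and undifferentiated spermatogonia genes in spermatogonia. They also differed in sign for lists not called in P5 against P1 controls (oocyte transcription factors, developmental factors and immediate early genes), in GO against NGO controls (blood genes) and in both differences of effects.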

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

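The results here were flagged because the effect of the Chd4 knockout differed between 2 ages or 2 oocyte stages in an interaction test with limma. These interactions were planned. The tests of mixed oocytes, scaling, Cre and somatic cell sources below were chosen after the results were seen.

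Between P5 and P1 the knockout effect differed for 64 genes (47 with a higher log2 fold change at P5, 17 with a lower one; 1505 at an unadjusted p under 0.05). Chd4 itself stood at 11.1% of the control mean in P1 knockouts and at 40.8% in P5 knockouts. An effect of age therefore cannot be told apart from an unlike degree of Chd4 loss. Of the P5 minus P1 cKO effect genes called 73.4% were higher, against 88% with voom and 60% with only the groups compared. The count was 16, 37, 42 and 34 without P1 control replicate 1, P1 control replicate 2, P1 knockout replicate 2 and P5 control replicate 2. The homeobox gene Noto had the largest loss at P1 and a smaller deficit at P5, at 3.52 TPM in knockouts and 79.1 in controls at P1 and at 167 and 304 at P5, a difference of 3.375 (limma adjusted p = 0.00654). It passed whichever library was left out, while each other gene named here for this difference missed the threshold without at least 1 library. Aadac differed by 3.684, Snord42b by 4.322, the histone gene H2bfm by 4.833 and Defb19 by 4.818, each low in P1 knockouts and higher in P5 knockouts. Itga11 (-2.461), Gsta4 (-2.1) and Ckb (-2.033) had a lower effect at P5. In knockouts and controls Itga11 was at 6.18 and 0.0632 TPM at P1 and at 0.270 and 0.0539 at P5, Ckb at 497.5 and 150.3 and at 406.7 and 503.4, and Gsta4 at 285 and 135 TPM at P1 and at 1050 and 2196 at P5. Eef1a1 differed by -0.731, at 1569 and 1361 TPM at P1 and 1241 and 1783 at P5. In the meiotic list 34 of 36 genes had a higher effect at P5 (1 past the test, 4 adjusted over the list alone; camera adjusted p = 5.765e-09; adjusted p = 0.333 with an estimated correlation). Both ages entered this difference, with 28 of the 36 below 0 in P1 knockouts (median -0.386, camera adjusted p = 0.0668) and 29 above 0 in P5 knockouts. Syce2, a synaptonemal complex gene, was the member past the test, with a difference of 1.01 (limma adjusted p = 0.0190). Supporting cell genes also had a higher effect at P5 (camera adjusted p = 0.04052; adjusted p = 0.427 with an estimated correlation), a call that was lost without 5 of the 8 libraries. Tbpl2 differed by 2.73 (limma adjusted p = 0.0308).

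Between growing and non-growing oocytes at P10 the knockout effect differed for 1527 genes (990 higher in growing oocytes, 537 lower). Of the P10 GO minus NGO cKO effect genes called 64.8% were higher in growing oocytes, against 53.6% with median scaling and 52.7% with quantile normalization, and the count was 901 and 900 without growing control replicates 1 and 2. Meiob, a meiotic recombination gene, was at 35.9 TPM in growing knockouts and 0.185 in growing controls, and at 0.383 and 11.1 in the non-growing ones (7.225). Serpinb6c (8.107), Lrrc19 (7.217) and Spint4 (7.021) were at 34.5, 29.0 and 69.1 TPM in growing knockouts and near 0 in growing controls, and at 0, 0.0652 and 33.6 in non-growing knockouts and 9.89, 8.85 and 44.7 in non-growing controls. Snord73a (7.129) was listed at 0 in growing controls and at 57.5 TPM in non-growing controls, and missed the threshold without 5 of the 8 libraries. Tcf7l2, a Wnt pathway transcription factor, was at 8.17 TPM in growing knockouts and 63.2 in growing controls, and at 17.6 and 0.611 in the non-growing ones (-6.287). Cpeb4 (-6.435), Psg16 (-6.408), Tmem274 (-6.305) and Fam107b (-6.279) went the same way, Fam107b at 18.5 and 128 TPM in growing and 28.05 and 1.945 in non-growing oocytes. From the lists, Sycp3 differed by 2.66 (limma adjusted p = 6.76e-05), Sohlh1 by 4.57 (0.000142), Pmaip1 by 4.98 (0.000882) and Crabp1 by 5.84 (0.00147), while none of the 21 lists passed.

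Genes that fall with growth lay higher in growing knockout oocytes with the controls split (medians 0.82 and 0.98), and on PC1 these libraries (111.92 and 135.47) lay between the non-growing libraries of P10 (31.22 to 55.27) and the growing controls (172.12 and 172.21), which non-growing oocytes mixed into them could bring. The tables argue against this for the 745 of 1866 raised genes (39.9%) that lay above both non-growing groups and for the 14.5% of 961 lowered genes that lay below both, while 670 raised genes (35.9%) lay below the higher non-growing mean. They also argue against mixing as the whole cause, since genes high in growing controls needed median shares of 0.571 to 0.685 and genes high in non-growing controls 0.103 to 0.268, at least 0.41 apart in each library and split. As part of the cause it cannot be told apart from a change in the oocytes for 95 genes high in non-growing controls. There the squared deviation from the best mixture (a share of 0.165) was 2 times the variance between replicates, at the bound. With a separately fitted share it was 9.8 times the pooled variance of limma, which leaves out the noise of the mixture's reference. The deviations of the 2 libraries had a Spearman correlation of 0.632, which the reference they share can bring. Neither value therefore decides on a single share. After quantile normalization 88.8% of the 2827 calls (2510) stayed called in the same direction, which argues against TPM scaling as the whole cause. These were 1567 of 1866 raised and 943 of 961 lowered genes, so scaling as part of the excess of raised genes stays open. The Gdf9-iCre transgene cannot be told apart from the loss of Chd4, since 0 of the P10 control libraries carried Cre. The loss of Chd4 stays open, and further explanations were not tested.

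Lists of somatic cell markers shifted up in knockout spermatogonia and in P5 and P10 NGO knockout oocytes, which cells of the gonad carried into the libraries could bring. None of these list calls held with an estimated correlation (camera adjusted p of 0.262 to 0.511), a run that also had only 2 or 8 degrees of freedom. Over all genes 0 of their members passed in spermatogonia, and only Inha at P5 and Gja1 in P10 NGO. Carried-over cells cannot be told apart from expression by the germ cells themselves, since the labels give no sort or gate and list members went both ways. Of the other members of the fixed lists, 5 of 24 stromal genes were higher by at least 25% of the TPM difference of Col1a1 in both knockout libraries, as were 1 of 34 supporting cell genes against Krt18, 1 of 34 against Inha at P5 and 2 of 34 against Gja1 in P10 NGO. Among genes picked after their values were seen, Dlk1, which is also imprinted, was higher by 479.8% and 373.7% of Col1a1 in the 2 libraries, Pdgfrb by 67.2% and 58.8% and Serpine2 by 56.2% and 34.9% of Krt18, while Col1a2 (8.8% and -0.1%), Col3a1 (1.7% and -5.2%) and Amh (0.4% and 0.5%) stayed far below. Of the other tested members, 12 of 13 stromal and 20 of 25 supporting cell genes lay above 0 in spermatogonia and 16 of 22 supporting cell genes at P5 and in P10 NGO each.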

How the results depend on the processing

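The voom fit and the fit without mitochondrially encoded genes were chosen after the data were seen, and the other settings before. Of 299 gene calls, 15 of 282 were lost with the filter at TPM 5, 21 with median scaling, 47 with no filter, 112 with only the groups compared, 33 with a pseudocount of 0.1, 18 with quantile normalization, 85 with a replicate block, 65 of 295 with voom and 1 of 288 without mitochondrial genes, and 135 missed the threshold without at least 1 library. Of 45 list calls an estimated correlation kept 1, in a run that also had fewer degrees of freedom.

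The counts below are those of P1 NGO DcKO vs Dctrl genes called (P1), P5 NGO DcKO vs Dctrl genes called (P5), P10 NGO GcKO vs Gctrl genes called, P10 GO GcKO vs Gctrl genes called, P3 male DcKO vs Dctrl genes called (spermatogonia), P5 vs P1 NGO in Dctrl genes called, P5 minus P1 cKO effect genes called and P10 GO minus NGO cKO effect genes called. With the filter at TPM 5 they were 190 at P1, 56 at P5, 56 in spermatogonia and 16 for the P5 minus P1 effect, where fewer genes were tested. With no filter they were 449 at P5, 211 in P10 NGO and 318 for P5 minus P1. With only the groups compared, which leaves 2 or 4 residual degrees of freedom, they were 0 at P5, 0 in P10 NGO, 1527 in P10 GO, 2358 for P5 against P1 controls, 10 for P5 minus P1 and 385 for GO minus NGO. A pseudocount of 0.1 gave 626 in P10 NGO and 139 for P5 minus P1, and -3.228 for Chd4 in P1 NGO DcKO vs Dctrl (limma adjusted p = 0.0626). Quantile normalization gave 939 in P10 NGO and 1 in spermatogonia. A replicate block gave 72 at P1, 0 at P5, 28 in P10 NGO, 543 for P5 against P1 controls and 25 for P5 minus P1, and -2.873 for the same gene (limma adjusted p = 0.0841). The replicate numbers showed no pairing, with correlations of -0.049 to 0.021. Voom gave 754 in P10 NGO, 1 in spermatogonia and 166 for P5 minus P1. Chd4 in P3 male DcKO vs Dctrl passed with the filter at TPM 5 (-2.522, limma adjusted p = 0.0155). Median scaling, the fold minimum and the fit without mitochondrial genes moved no count by over 1.5 times. Except where fewer genes or libraries were tested, the cause was not tested.

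Only quantile normalization removed the direction of a change, with Dppa3 in P10 GO at 0, Dppa5a in P10 GO at 0 and Dppa3 in the GO minus NGO effect at 0 (limma adjusted p = 1 each). This follows from its construction, which gives genes of the same rank the same value.

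Without a library, which leaves 1 in its group, the counts ranged from 71 to 235 at P1, 22 to 396 at P5, 282 to 1260 in P10 NGO, 1744 to 2520 in P10 GO, 0 to 24 in spermatogonia, 249 to 486 for P5 against P1 controls, 3635 to 4429 for GO against NGO controls, 16 to 90 for P5 minus P1 and 900 to 2168 for GO minus NGO. Chd4 in P1 NGO DcKO vs Dctrl ranged from -3.31 to -2.435 and Chd4 in P3 male DcKO vs Dctrl from -2.70 to -2.345.

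In simulated data 100 genes were changed at each fold, all with a mean above 5 TPM in the reference group. Of these the test recovered 6 to 9 at 2 times and 36 to 49 at 4 times in the oocyte knockout comparisons, and 25 and 69 in spermatogonia. It recovered 3 and 27 for P5 against P1 controls, 11 and 36 for GO against NGO controls, 1 and 5 for P5 minus P1 and 0 and 21 for GO minus NGO. Unchanged genes made up more than 5% of the calls at P1 (9), at P5 (5), in P10 GO (5), in spermatogonia (13), for P5 against P1 controls (4), for GO against NGO controls (3) and for GO minus NGO (2). Small changes are therefore missed at this group size. Changes in genes near 0 TPM, and a comparison with as many changes as P10 GO, were not simulated, so these shares do not carry over to them. Depth was 15.33 to 27.01 M reads in oocytes, and what it limits was not tested.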

Other observations

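The gene list of the 2-cell embryo and the tests of the X chromosome and of the age state were chosen after the results were seen, and each is a hypothesis of this section.

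Zscan4 and Usp17l genes, known from the 2-cell embryo, rose in growing knockout oocytes. Of 18 tested genes of a 2-cell list written after Zscan4a and Usp17lb had been seen, 12 rose and 0 fell in P10 GO (median 4.35, camera adjusted p = 1.08e-08; adjusted p = 0.012 with an estimated correlation). In P10 NGO Zscan4a rose from 0.179 to 9.28 TPM (limma adjusted p = 0.0423), and Zscan4c, Zscan4d and Zscan4f were at 10.48, 8.33 and 2.18 TPM in knockouts and 0.465, 0.354 and 0.205 in controls, not past the test. The list as a whole was not called outside P10 GO (0.403 to 0.463). Without the Zscan4 genes 8 of 14 rose in P10 GO (camera adjusted p = 5.74e-05; adjusted p = 0.013 with an estimated correlation), which decides nothing about a wider set, since the list still held the Usp17l genes that prompted it. Without both families 3 of 9 rose, Tdpoz1, Zfp352 and Pramef25, with a median of -0.38 and a camera adjusted p of 0.331 (0.387 with an estimated correlation). The rise is shown for these 2 families, whose paralogs can share reads. No predicted gene model was among the tested list members, and the naming rule leaves such models out. Some of them also rose in P10 GO, such as Gm2022 from 0.151 to 327 TPM and Gm8300 from 0.248 to 271, both chosen after their values were seen. The list therefore does not limit the rise to the 2 families, and a wider set stays open.

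Among the genes that rose at P5, 27 of 201 lay on the X chromosome (13.4%) against 4.1% of the other tested genes (Fisher's exact adjusted p = 7.75e-07), a count that includes the genes that prompted it. Without the 3 X-linked genes named at P1 and P5 (Fthl17e, Chst7 and Magea5) it was 24 of 198 (12.1%, adjusted p = 1.24e-05), 49 of 322 without control replicate 1 (3.1e-14), 3 of 17 without control replicate 2 (0.106), 3 of 61 without knockout replicate 1 and 0 of 19 without knockout replicate 2. The largest of these adjusted p was 1, so the hypothesis stays open for P5. At P1 it was 10 of 168 (6.0% against 4.1%, adjusted p = 0.3) and 8 of 166 without the 3 genes (adjusted p = 1), so P1 stays open too. In P10 GO it was 119 of 1803 (6.6% against 3.9%, adjusted p = 1.63e-06), and in P10 NGO 14 of 203 (0.121), where genes that fell held fewer (1 of 179, 0.6% against 4.2%, adjusted p = 0.0152). In spermatogonia, at an unadjusted p under 0.05, it was 118 of 2018 higher genes (5.8% against 3.8%, adjusted p = 0.000105) and 20 of 905 lower ones (2.2% against 4.1%, adjusted p = 0.00762). The P10 and spermatogonia counts were not repeated without each library, and that of P10 GO includes the named X-linked genes Bex3, Rhox2d and Mir3473a. Fisher's exact test treats genes as independent, while X-linked paralogs such as Rhox2 genes can share reads. These counts therefore leave the hypothesis open too.

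At P5 the oocyte growth list shifted down and the meiotic list up in knockouts, which knockout oocytes that keep part of the P1 state could show. Neither list call held with an estimated correlation (camera adjusted p = 0.262 each). Over all genes 2 of 35 growth genes fell and 4 of 36 meiotic genes rose. Lists of 200 genes that rose or fell with age were made with 1 P5 control library and tested against the other. Each of the 4 tests stayed on the same side of the threshold with an estimated correlation. The genes that fall with age were higher in knockouts in both splits (medians 0.30 and 0.38, camera adjusted p = 4.79e-09 and 1.95e-19). The genes that rise with age were lower in 1 split (-0.60, 1.29e-18) and not past the test in the other. There the median was -0.10 (106 below and 94 above 0) and the camera direction was up, against the hypothesis (adjusted p = 0.205), so the largest of the 4 values, 0.205, leaves this hypothesis open.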
